A study of Mus musculus with 16 samples.

How the data were processed

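RNA sequencing libraries from 16 mice with T cell acute lymphoblastic leukaemia (T-ALL) were analysed, 1 library per mouse. The labels name a C57Bl6 strain, total RNA extracted with a MagMax-96 kit and stranded mRNA libraries made with a TruSeq kit. The organ the cells came from, the sex and age of the mice and any sequencing batch are not given in the sources used here.

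The deposited values are raw counts, 1 table per mouse with 41214 genes under Ensembl identifiers. Per the submitters' processing notes, the tools were TopHat2 2.0.10, SAMtools, HTSeq and DESeq, and the builds mm10 and GRCm38, which name the same assembly. The notes give no order or role for these tools, and the annotation release, the strand setting of the counter and any removal of duplicate reads are not given in the sources used here. Without a known strand setting, genes that overlap on opposite strands cannot be told apart and are named as overlapping where they are reported. Each deposited count table ends with 5 totals that name no gene. Alignments that did not map uniquely took 45.81% to 63.74% of a library's total, reads outside annotated genes 14.22% to 21.5% and reads over several genes 0.138% to 0.331%. These totals were left out of library sizes and tests, and the genes kept 20.57% to 39.64%. Because reads shared between near-identical copies drop out as not unique, counts of gene families such as the globins are uncertain.

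Gene names, biotypes and coordinates were taken from GENCODE mouse release M21 on GRCm38, which held 40340 of the identifiers. The other 874 were tested under their identifiers. The libraries held 36463524 to 68523196 gene counts (median 50171983), which detected 19629 to 25387 genes with at least 1 count. Intervals and detection floors given with single genes cover counting error only, with a confidence level of 95% and a floor of 3 counts over the group.

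Mice were grouped by Miz1 status, p53 status and induction by ICN, as the labels give them, and by a Lck or Vav suffix that the titles of the Miz1 mutant mice carry and the labels do not explain. This made 8 groups of 2 mice. Replicate numbers follow accession order and only name a library. Counts were fitted with edgeR 4.0.16 under R 4.3.3 (TMM scaling, factors 0.952 to 1.05; filterByExpr, which left 17470 genes; quasi-likelihood fit over 8 groups with 8 residual degrees of freedom, a common dispersion of 0.208 and median prior degrees of freedom of 3.34). Contrasts were tested with the quasi-likelihood F test, and p-values were adjusted with the Benjamini-Hochberg method over all genes, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Levels are TMM-normalised counts on the CPM scale, given as mean ± SD over mice, and log2 CPM used a prior count of 2.

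The contrasts were Miz1 deltaPOZ against Miz1 wt within each of 3 backgrounds (ICN with p53 wt, ICN with p53 ko, and p53 ko without ICN), their average, and the difference between both ICN backgrounds. Further contrasts were p53 ko against p53 wt among ICN leukaemias, ICN against no ICN among p53-ko leukaemias, and Lck against Vav. The Miz1 contrasts of the 3 backgrounds compare no library in common, but all contrasts share 1 estimate of spread per gene. The p53, ICN and suffix contrasts reuse libraries of the Miz1 contrasts, so counts of calls were not compared across those.

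Gene lists numbered 26 and covered pathways (p53 targets, Notch targets, cytosolic ribosomal proteins, ribosome biogenesis and MYC targets, cell cycle, Bcl2 family, autophagy and vesicle transport, genes reported as Miz1 targets, IL-7 and JAK-STAT signalling, nucleoside analogue metabolism, interferon response, cholesterol synthesis, unfolded protein and integrated stress response, glycolysis and hypoxia, immediate early and tissue handling genes, mitochondrially encoded proteins), thymocyte stages and leukaemia genes (immature double-negative and progenitor genes, double-positive and maturing thymocyte genes, leukaemia transcription factors and oncogenes), and markers of other cells (B cells, macrophages and dendritic cells, neutrophils and granulocytes, erythroid cells, endothelium and stroma, thymic epithelium, NK and cytotoxic cells). Lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. Camera with an estimated correlation and fry were alternatives. Of all list calls, 3 held with an estimated correlation: the macrophage list between p53 genotypes, and the erythroid and immature thymocyte lists between ICN and no ICN. Members of a list were also adjusted over the list alone.

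Genes were named by a rule. A named gene had an adjusted p under 0.05, was protein coding, had a mean log2 CPM of at least 0, was not a receptor gene segment, Y-linked or Xist, and had all libraries of one side above all of the other in at least 1 background with no background the other way. Up to 12 genes per direction with the largest change were taken. Where none passed, the 5 genes with the lowest unadjusted p are given as values. Up to 4 members of each list with the lowest p, and Zbtb17, Trp53 and Notch1, were added. Some genes that this rule names are not reported here. The contrasts, lists, naming rule and most alternatives were set before the data were examined.

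Single genes of the averaged Miz1 contrast were also tested in R by an exact permutation of Miz1 status within backgrounds (1350 arrangements), counting changes of either sign. Counts were joined and replicate correlations computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives were DESeq2 1.42.0 with a Wald test, median-of-ratios scaling, no filter on low counts, removal of receptor segments and sex-linked genes, a fit to the compared groups only, 6 groups with the Lck and Vav suffixes pooled, and removal of each library in turn. Alternatives chosen after seeing the data were an additive model for the averaged Miz1 contrast, erythroid and granulocyte scores as covariates, and repeats of the list tests without single libraries or with other scaling.

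The tests were tried on simulated counts drawn from the real means and library sizes, with 100 genes per fold size. The edgeR test recovered 46% of genes changed 4-fold and 4% of those changed 2-fold in the Miz1 contrast of the ICN p53-wt background, and 38% and 0% in the background without ICN. It recovered 73% and 46% in the averaged Miz1 contrast, 57% and 20% in the p53 contrast, and 49% and 12% in the ICN contrast. Among unchanged genes it called 1, 2, 8, 0 and 6 in these contrasts, in the same order. DESeq2 recovered more (65%, 62%, 87%, 78% and 72% of the 4-fold genes) and called 54, 69, 79, 51 and 61 unchanged genes. Camera found 5 of 5 raised lists and called 0 unchanged lists. The simulated genes were drawn independently of each other, so this does not test camera on lists whose members move together.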

Results

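Gene expression was measured by RNA sequencing in T-ALL samples from 16 mice, in 8 groups of 2 mice each. The mice carried wild-type Miz1 (6 mice) or a Miz1 protein without its POZ domain (deltaPOZ, 10 mice), wild-type p53 (6 mice) or no p53 (ko, 10 mice), and had leukaemia induced by ICN, an activated Notch, in 12 mice or without ICN in 4 mice. Miz1 is a zinc finger transcription factor encoded by Zbtb17, and its POZ domain is needed for stable binding to DNA. The deltaPOZ mice are split by the suffixes Lck and Vav in their titles. The libraries held 36463524 to 68523196 gene counts. The labels name separate mice, so p-values measure the spread between mice. Replicate pairs had Spearman correlations of 0.927 to 0.983 over genes. The first principal component held 47.3% of the variance and parted the 4 libraries without ICN (138.6 to 169.9) from the 12 with ICN (-71.7 to -33).

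The targeted genes were examined first. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873 on GRCm38) lay at 70.2, 86.7, 93.4, 104.9, 113.5 and 92.2 CPM in the p53-wt libraries and at 7.3 to 30.6 CPM in all 10 p53-ko libraries, so every library followed its p53 label. Zbtb17 (ENSMUSG00000006215, chromosome 4, 141444654 to 141467930, overlapping Spen on the opposite strand) lay at 51.8 and 42.9 CPM in ICN Miz1-wt p53-wt libraries, at 38 to 43.2 CPM in their deltaPOZ counterparts, at 50.5 and 48.5 CPM in ICN Miz1-wt p53-ko libraries and at 44.2 to 63.3 CPM in their deltaPOZ counterparts. Without ICN it lay at 137.8 and 78.6 CPM with Miz1 wt and at 56.9 and 87.5 CPM with deltaPOZ. Its averaged deltaPOZ change of -0.25 (log2; SE 0.15, n = 10 and 6) did not pass (adjusted p = 1). The counts cover whole genes, so a deletion of the POZ exons need not show in them and this check of the Miz1 labels is weak. Notch1 (ENSMUSG00000026923, chromosome 2, 26457903 to 26516663) lay at 277.4 to 961 CPM in the 12 ICN libraries and at 539.4, 2105.4, 1877.2 and 1497 CPM in those without ICN, and the counts do not tell a transgene from the mouse gene.

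The main question of the series is how loss of the Miz1 POZ domain alters expression in T-ALL. Averaged over the 3 backgrounds, 3 genes fell in deltaPOZ leukaemias (10 against 6 mice). Znhit3, which encodes a zinc finger protein of snoRNP assembly, was 3.26-fold lower (log2 -1.70, SE 0.21, adjusted p = 0.0323). Snx18, a sorting nexin of endocytic membranes, was 2.66-fold lower (log2 -1.41, SE 0.17, adjusted p = 0.0323). Hfm1, a meiotic DNA helicase, was 8.31-fold lower (log2 -3.06, SE 0.38, adjusted p = 0.0323) from low levels of 0.603 to 6.98 CPM in the Miz1-wt groups. Its fall was largest without ICN (log2 -6.04) and in ICN p53-wt mice (-2.60), and in ICN p53-ko mice it lay at 0.603 CPM with Miz1 wt against 0.437 and 0.401 CPM (-0.52, SE 0.59). Znhit3 (ENSMUSG00000020526, chromosome 11, 84910950 to 84916366) overlaps the end of Myo19 on the opposite strand, which itself did not pass (log2 0.04, SE 0.22, adjusted p = 1). Its group means (n = 2 each) fell from 23.2 CPM with Miz1 wt to 12 (Lck) and 10.6 CPM (Vav) in the ICN p53-wt background, from 21.8 to 12.6 and 10.5 CPM in the ICN p53-ko background, and from 30.6 to 3.42 CPM without ICN. Snx18 (ENSMUSG00000042364, chromosome 13, 113592179 to 113618564) lay at 42.4, 53.2 and 39.6 CPM in the Miz1-wt groups and at 9.54 to 40.2 CPM in the deltaPOZ groups, highest in the ICN p53-ko Lck group. Hfm1 (ENSMUSG00000043410) lies on chromosome 5 at 106840192 to 106926321.

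Among 18 genes reported as Miz1 targets, 0 changed over all genes and 3 fell adjusted over the list alone. These were Ambra1, a regulator of autophagy (log2 -0.71, SE 0.12, list-adjusted p = 0.00122), Vamp4, a SNARE of vesicle transport (-0.87, SE 0.19, 0.00373), and Rpl22, a ribosomal protein of the large subunit (-0.74, SE 0.13, 0.00153). Group means of Ambra1 were 77, 78.7 and 93.5 CPM with Miz1 wt and 40.8 to 56.2 CPM with deltaPOZ (n = 2 each). For Ambra1 and Vamp4 every Miz1-wt library lay above every deltaPOZ library of its background in all 3 backgrounds. Chance gives this in 1 of 1350 arrangements (exact permutation p = 0.000741, the smallest these arrangements can give). For Rpl22 the exact permutation p was 0.00519. The list as a whole was lower (camera adjusted p = 1.08e-05, adjusted p = 0.177 with an estimated correlation). Other lists had members that passed when adjusted over the list alone. Rpl22l1, the paralog of Rpl22, rose 3.13-fold (log2 1.65, SE 0.29, 0.00678) and was the only one of 80 ribosomal protein genes to rise, while Rpl22 fell. Of 17 genes of the Bcl2 family, Bcl2l2, an inhibitor of cell death, rose (0.88, SE 0.21, 0.0213). Of 23 Notch targets, Cr2 (2.70, SE 0.55), which is also on the B cell list, and Hey1 (2.21, SE 0.62) rose.

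Of 19 B cell markers, 0 changed over all genes and 8 rose adjusted over the list alone, among them Igkc (2.34), Cd79b (2.24) and Cd79a (1.62), which encode parts of the B cell receptor (camera adjusted p = 1.14e-21, adjusted p = 0.177 with an estimated correlation). The mean log2 CPM of these markers lay at 3.19 to 4.76 in the 8 ICN deltaPOZ libraries and at 4.17, 2.25, 2.3 and 0.52 in the 4 ICN Miz1-wt libraries. Without ICN it lay at 0.66 and 1.17 with deltaPOZ and at 0.7 and 0.47 with Miz1 wt, and the list did not pass there (camera adjusted p = 0.494). Cholesterol synthesis genes were lower as a group (camera adjusted p = 1.5e-06, adjusted p = 0.479 with an estimated correlation), and ribosomal protein genes were higher (6.67e-05, adjusted p = 0.881 with an estimated correlation). Neutrophil markers (0.00569, adjusted p = 0.881 with an estimated correlation) and endothelial and stromal markers (0.00298, adjusted p = 0.811 with an estimated correlation) were higher and autophagy genes lower (0.00544, adjusted p = 0.627 with an estimated correlation). Not all backgrounds shared these rises. The neutrophil mean lay at 1.68 to 3.05 with deltaPOZ and at 3.85 and 0.48 with Miz1 wt in ICN p53-wt mice. The endothelial and stromal mean lay at 0.4 to 1.33 with deltaPOZ and at 0.12 and 1.52 with Miz1 wt in ICN p53-ko mice. The fall of the cholesterol synthesis genes was uneven too. Their mean lay at 4.63 to 5.04 with deltaPOZ and at 4.85 and 4.7 with Miz1 wt in ICN p53-ko mice. Without ICN it lay at 4.57 and 5.5 with deltaPOZ and at 5.66 and 5.55 with Miz1 wt. The 3 calls depended on single mice, while the folds moved little over the 16 fits that left out 1 library each (log2 -1.82 to -1.63 for Znhit3, -1.52 to -1.26 for Snx18 and -3.43 to -2.84 for Hfm1, adjusted p up to 0.127): 0 remained without any 1 of 9 libraries (both replicates of ICN Miz1-wt p53-wt, ICN Lck p53-wt and ICN Lck p53-ko, replicate 1 of noICN Miz1-wt, noICN Vav and ICN Vav p53-ko), 1 or 2 genes were called without each of the ICN Miz1-wt p53-ko or ICN Vav p53-wt libraries, and 20 and 15 genes were called without replicate 2 of noICN Miz1-wt or noICN Vav. With erythroid and granulocyte scores as covariates, chosen after seeing the data, 1 gene was called (Snx18), and an additive model called 0. At an unadjusted p under 0.05 there were 859 genes (4.92% of those tested), and DESeq2 called 134. With no change at all, a share of 0.05 of the genes would reach that p, so this number shows no excess.

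**Figure D1:**
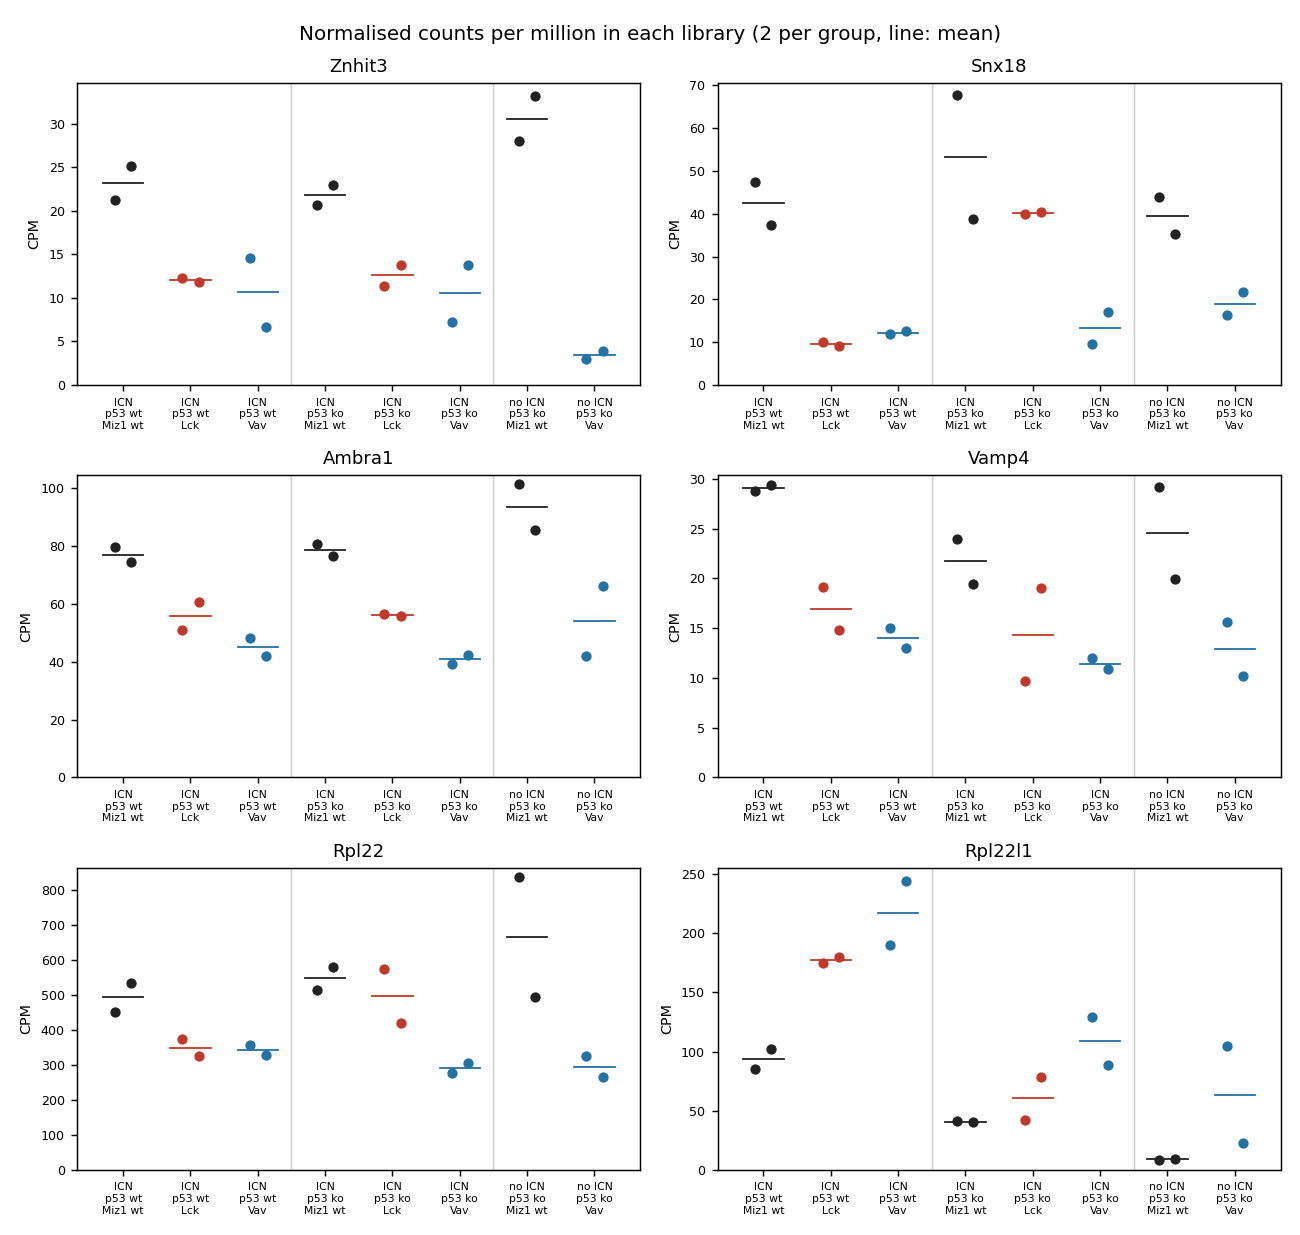
Normalised CPM (y axis) of Znhit3, Snx18, Ambra1, Vamp4, Rpl22 and Rpl22l1 in each library, 1 point per mouse and a line at the group mean, for the 8 groups on the x axis. Group means of Znhit3 lie at 21.8 to 30.6 CPM with Miz1 wt and at 3.42 to 12.6 CPM with deltaPOZ.

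In ICN leukaemias with wild-type p53 (4 deltaPOZ against 2 Miz1-wt mice), edgeR called 0 genes, and DESeq2 called 16, all lower. At an unadjusted p under 0.05 there were 327 genes (1.87%), no more than a share of 0.05 expected with no change. The lowest p belonged to Ldhb, a subunit of lactate dehydrogenase, at 13.9 CPM with Miz1 wt, 6.89 CPM in Lck and 0.622 CPM in Vav mice (log2 -2.75, SE 0.34, adjusted p = 0.0775). It was followed by Snx18 (-1.97, SE 0.28), Lrp12 (-3.35), Rsrc1 (-2.75) and Gne (-1.20), none of which passed. B cell markers were higher as a group with 0 of 19 members passing over all genes or over the list alone (camera adjusted p = 7.48e-09, adjusted p = 0.593 with an estimated correlation), as were endothelial and stromal markers (0.00373, adjusted p = 0.622 with an estimated correlation) and macrophage markers (0.00398, adjusted p = 0.593 with an estimated correlation). The reported Miz1 targets were lower as a group (camera adjusted p = 0.0184, adjusted p = 0.593 with an estimated correlation). The double-positive and maturing thymocyte genes were lower too (0.0184, adjusted p = 0.6 with an estimated correlation). So were the cholesterol synthesis genes (0.0184, adjusted p = 0.682 with an estimated correlation) and the autophagy genes (0.0342, adjusted p = 0.6 with an estimated correlation). The cholesterol mean (log2 CPM) lay at 4.25 to 4.91 with deltaPOZ, lowest in replicate 2 of ICN Vav p53-wt, and at 4.75 and 4.91 with Miz1 wt. The count became 1 without replicate 1 of ICN Miz1-wt p53-wt or of ICN Vav p53-wt.

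In ICN leukaemias without p53 the same contrast called 1 gene. Sox11, a transcription factor of neural progenitors that is expressed in some lymphoid tumours, lay at 8.75 ± 3.68 CPM in Miz1-wt mice (n = 2, 792 counts) and at 0.0154 ± 0.0104 CPM in deltaPOZ mice (n = 4, 3 counts), a pooled ratio of 603 (counting interval 206 to 2930; log2 -9.00, SE 0.87, adjusted p = 0.00687). Sox11 (ENSMUSG00000063632) lies on chromosome 12 at 27334264 to 27342574. Of 19 B cell markers, 0 passed over all genes and 11 rose adjusted over the list alone, among them Cr2 (log2 5.03), Igkc (4.85), Ms4a1 (4.22) and Fcer2a (4.21). Igkc lay at 4.88 CPM in Miz1-wt mice and at 129.9 and 151.5 CPM in Lck and Vav mice. The B cell list passed camera (adjusted p = 4.96e-30, adjusted p = 0.182 with an estimated correlation). Ribosome biogenesis genes were higher as a group (1.22e-10, adjusted p = 0.623 with an estimated correlation), as were neutrophil markers (8.17e-07, adjusted p = 0.623 with an estimated correlation). Ribosomal protein genes were also higher (0.00487, adjusted p = 0.839 with an estimated correlation). The reported Miz1 targets were lower (0.00448, adjusted p = 0.426 with an estimated correlation), as were the mitochondrially encoded genes (0.00461, adjusted p = 0.641 with an estimated correlation), autophagy genes (0.0154, adjusted p = 0.623 with an estimated correlation) and NK markers (0.0352, adjusted p = 0.623 with an estimated correlation). The NK mean (log2 CPM) was lower only in Vav mice, at 1.07 and 1.2 against 2.14 and 2.35 with Miz1 wt. In Lck mice it was higher, at 2.47 and 2.73. At an unadjusted p under 0.05 there were 660 genes (3.78%, no more than a share of 0.05 expected with no change), and DESeq2 called 127. The call on Sox11 was lost without any 1 of the 4 ICN deltaPOZ p53-ko libraries (log2 -10.19 to -8.54 there, against -9.00; adjusted p = 0.00432 to 0.269 over all fits that left out 1 library) and with erythroid and granulocyte scores as covariates. The counts without the ICN Miz1-wt p53-ko libraries were 3 (replicate 1) and 2 (replicate 2), and without replicate 1, which had the most alignments that were not unique (63.74%), the ribosome biogenesis (adjusted p = 0.845), ribosomal protein (0.402) and mitochondrial lists (0.845) reversed.

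Without ICN (2 deltaPOZ Vav against 2 Miz1-wt mice, all p53 ko), edgeR called 0 genes, with 1341 (7.68%) at an unadjusted p under 0.05, and DESeq2 called 241. The lowest p belonged to Phlpp2, a phosphatase of the AKT pathway (0.917 CPM with Miz1 wt, 8.11 CPM with deltaPOZ; log2 3.14, SE 0.42), and to Znhit3 (-3.16, SE 0.43), Gpr146 (2.82), Hfm1 (-6.04, SE 0.85) and M1ap (5.04), all with an adjusted p of 0.0598. Adjusted over the list alone, Rpl22 fell (-1.18, SE 0.26, 0.0149) and Rpl22l1 rose (2.88, SE 0.57, 0.0261), from 8.63 to 63.4 CPM. Ambra1 fell (-0.79, 0.0399), and Bcl2l2 (2.29, SE 0.40, 0.00218), the Notch target Hey1 (5.97, 0.0216) and the T cell surface gene Cd5 (2.22, 0.0498) rose. Cholesterol synthesis genes were lower as a group (camera adjusted p = 2.06e-05, adjusted p = 0.869 with an estimated correlation), as were macrophage markers (0.000182, adjusted p = 0.464 with an estimated correlation), ribosome biogenesis genes (0.00191, adjusted p = 0.869 with an estimated correlation), which were higher in ICN p53-ko mice, and glycolysis genes (0.0395, adjusted p = 0.869 with an estimated correlation). The cholesterol mean (log2 CPM) lay at 4.57 and 5.5 with deltaPOZ and at 5.66 and 5.55 with Miz1 wt. Replicate 1 of noICN Vav thus carried most of this fall. Erythroid markers were higher (0.00899, adjusted p = 0.869 with an estimated correlation), 3 of them adjusted over the list alone. The count became 108 without replicate 2 of noICN Vav, and 7 and 32 without replicate 1 and 2 of noICN Miz1-wt.

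The effect of deltaPOZ was compared directly between both p53 backgrounds of the ICN leukaemias. No gene passed: edgeR called 0, with 454 (2.6%) at an unadjusted p under 0.05, and DESeq2 called 30. That percentage is no more than a share of 0.05 expected with no change. Sox11 (log2 difference -10.66) had the lowest adjusted p of 0.143, followed by Mtmr7 (5.20), Ldhb (2.28), Serpinb8 (-5.34) and Etv6 (-1.58). Of the lists, 4 differed by camera. The median log2 change of B cell markers with deltaPOZ was larger in p53-ko than in p53-wt leukaemias (2.01 against 0.72, adjusted p = 1.39e-10), as was that of ribosome biogenesis genes (0.34 against 0.09, 0.000131), although 0 members of either list passed in p53-wt leukaemias and 0 of the latter in p53-ko ones. The median log2 change of neutrophil markers with deltaPOZ was 0.54 in p53-ko and -0.84 in p53-wt leukaemias (camera adjusted p = 4.76e-05). That of mitochondrially encoded genes was -0.65 and 0.28 (camera adjusted p = 0.00021). In p53-wt mice the neutrophil mean log2 CPM lay at 1.68 to 3.05 with deltaPOZ, between 3.85 and 0.48 with Miz1 wt. By that measure the neutrophil markers did not fall there. Without single libraries of the Miz1-wt pairs the neutrophil difference (0.604 and 0.563) and the ribosome biogenesis difference (0.206) changed direction, and B cell and mitochondrial genes reached an adjusted p of 0.253 and 0.427 over the fits that left out 1 library. Each had an adjusted p = 0.944 with an estimated correlation.

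The Lck and Vav suffixes of ICN deltaPOZ leukaemias were compared with each other (4 against 4 mice). Interferon response genes were higher in Lck mice as a group (camera adjusted p = 1.85e-11, adjusted p = 0.351 with an estimated correlation). Of 34 such genes 0 passed over all genes, and Iigp1 (log2 2.14) and Zbp1 (1.11), an immunity-related GTPase and a nucleic acid sensor, rose adjusted over the list alone (0.0377 each). NK markers were also higher in Lck mice (camera adjusted p = 1.5e-07, adjusted p = 0.303 with an estimated correlation), and ribosome biogenesis genes lower (3.33e-08, adjusted p = 0.527 with an estimated correlation). Neutrophil markers were higher on average (3.33e-08, adjusted p = 0.426 with an estimated correlation). Their mean log2 CPM lay at 7.19 and 6.69 in Lck against 3.43 and 4.74 in Vav p53-ko mice. In p53-wt mice it lay at 2.62 and 1.72 in Lck against 3.05 and 1.68 in Vav mice. For single genes edgeR called 0, with 551 (3.15%) at an unadjusted p under 0.05, and DESeq2 called 22. That percentage is no more than a share of 0.05 expected with no change. The lowest p belonged to Prdm16 (-3.49) and Ldhb (1.74), at an adjusted p of 0.551, followed by Lsp1 (1.88), Iigp1 and Myrfl (2.74), at an adjusted p of 1. The count became 1 without replicate 2 of ICN Vav p53-wt.

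Loss of p53 was compared among the ICN leukaemias (6 against 6 mice). Cdkn2a, which encodes the tumour suppressors p16INK4a and p19ARF, rose from 0.914 ± 0.494 to 49.4 ± 19.7 CPM (log2 5.81, SE 0.44, adjusted p = 0.000302). Cdkn2a lies on chromosome 4 at 89274471 to 89294653 (ENSMUSG00000044303). Trp53 fell 4.18-fold, from 93.5 ± 15.0 to 22.5 ± 6.64 CPM (log2 -2.06, SE 0.24, adjusted p = 0.009). In all, 21 genes rose and 13 fell. Further genes that rose were Tmem151b (43.5-fold, 0.03; 22 ± 34.1 CPM over the p53-ko mice, from 1.07 to 90.3; it overlaps Tcte1), the myeloid genes Ccl24 (7.25-fold, 0.0475) and Fcgr3, a low-affinity IgG receptor (3.61-fold, 0.0267), the calcium-binding S100a4 (4.37-fold, 0.019; it overlaps Gm42674), and Pdlim4, Gna15, Ctsl, Gm6685, Gm10282 and D430041D05Rik. Genes that fell included the NK receptor Klrb1c (6.47-fold, 129 ± 73.8 to 21.2 ± 23.9 CPM, 0.0478; it overlaps Gm44511), the kinase Pnck (5.09-fold, 0.0143), Rapgef2 (log2 -1.91, 0.036), Shisa5 (-0.84, 0.0478), a p53-induced gene, and Gm14569 (-2.80, 0.0268).

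Of 40 p53 targets 0 rose or fell, over all genes or adjusted over the list alone (camera adjusted p = 0.982). Members moved both ways, so this does not show unchanged p53 targets (fry adjusted p = 0.000881 for a change in either direction). Zmat3 lay at 3.86 to 12.4 CPM in p53-ko and at 15.1 to 33.9 CPM in p53-wt mice (log2 -1.78, adjusted p = 0.169) and Ccng1 was lower (-0.62, SE 0.20), while Plk2 (1.52) and Fas (1.77) were higher, with none of the 4 passing. All 19 neutrophil markers rose adjusted over the list alone and 0 over all genes, among them the granule genes Mpo (log2 3.33), Elane (3.41) and Camp (3.43) and the calcium-binding S100a8 (2.77) (camera adjusted p = 2.49e-16, adjusted p = 0.322 with an estimated correlation). Their mean log2 CPM lay at 0.48 to 3.85 in p53-wt and at 0.6 to 7.19 in p53-ko ICN libraries. Of 21 macrophage markers 1 rose over all genes (Fcgr3) and 11 adjusted over the list alone, such as Lyz2 (2.03), Fcgr1 (1.54) and Csf1r (0.73). This call held with an estimated correlation (1.1e-09, adjusted p = 0.0467 with an estimated correlation). Fcgr3 is itself on the macrophage list. Whether Ccl24 and S100a4 rose in the same libraries as these markers was not tested. Among Notch targets, Hey1 (-2.92; 8.33 against 59 CPM), Nrarp (-1.74; 172 against 597 CPM) and Cr2 (-1.78) fell adjusted over the list alone, while Fjx1 (3.25), Rhou (2.49) and Igf1r (1.52) rose (camera adjusted p = 0.478). Of 25 leukaemia transcription factors and oncogenes, 1 rose over all genes (Cdkn2a) and 4 adjusted over the list alone, with Cdkn2b (2.76, 0.0013), Hoxa9 (2.36) and Lmo1 (2.83) beside it (0.00532, adjusted p = 0.175 with an estimated correlation). Of 38 cell cycle genes 0 passed, and the list was higher by camera (2.42e-08, adjusted p = 0.175 with an estimated correlation). Of the double-positive and maturing thymocyte genes, S1pr1, Cd5 (-1.01), Satb1 (-0.77) and Tcf12 (-0.67) fell adjusted over the list alone (camera adjusted p = 0.0663).

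At an unadjusted p under 0.05 there were 2705 genes (15.48%), and DESeq2 called 1065. The higher genes made up 61.8% of calls, 48.6% with Lck and Vav pooled and 49.7% in a fit of the compared groups only. The count of 34 depended on single mice, from 2 without replicate 1 of ICN Lck p53-wt to 132 without replicate 2 of ICN Miz1-wt p53-ko; it fell to 6 to 22 without replicates 1 and 2 of ICN Miz1-wt p53-wt, ICN Vav p53-wt, noICN Miz1-wt and ICN Lck p53-ko, replicate 2 of ICN Lck p53-wt and ICN Vav p53-ko, and replicate 1 of ICN Miz1-wt p53-ko, and was 65 without replicate 2 of noICN Vav. Cdkn2a stayed called in all 16 such fits (0.00031 to 0.00932), and Trp53 in 14 (0.00342 to 0.0578), being lost without replicate 1 of ICN Lck p53-wt (0.0578) or replicate 2 of ICN Lck p53-ko (0.0504). Of the other named genes, Gm6685 stayed called in 15, Pnck in 10, Gm14569 in 9, Tmem151b in 8 (log2 4.31 to 5.78), and the rest in 2 to 6. With erythroid and granulocyte scores as covariates, chosen after seeing the data, 2 genes were called, Cdkn2a among them, and Trp53 did not pass (log2 -1.87, SE 0.33, against -2.06, SE 0.24, before; adjusted p = 0.341, range over all alternatives 3.69e-21 to 0.341), as its spread rose while the fold stayed near.

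**Figure D2:**
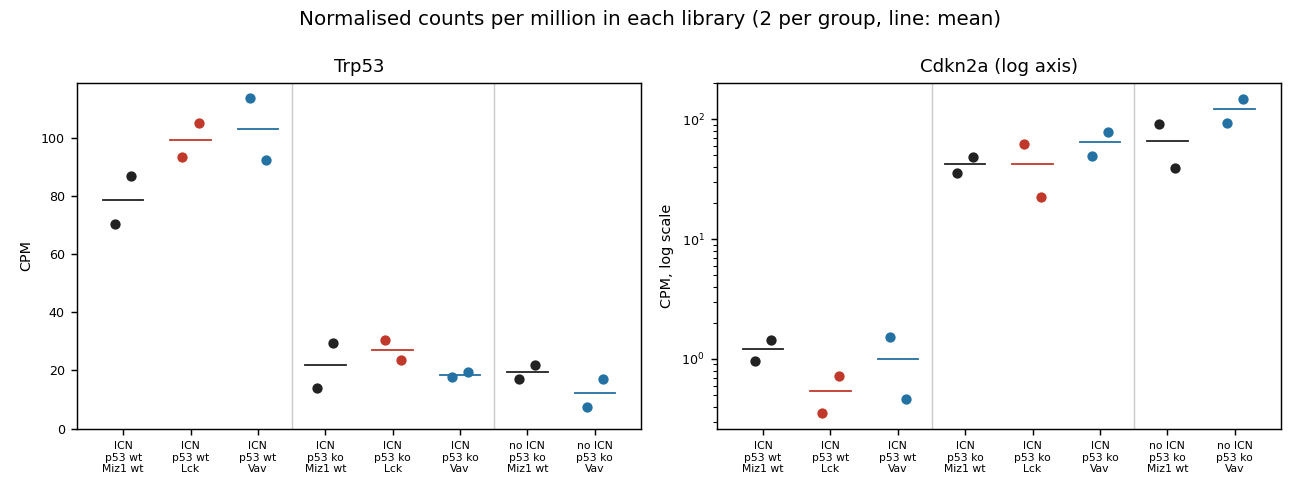
Normalised CPM (y axis) of Trp53 (linear axis) and Cdkn2a (log axis) in each library, 1 point per mouse and a line at the group mean, for the 8 groups on the x axis. Trp53 lies at 70.2 to 113.5 CPM in the p53-wt libraries and at 7.3 to 30.6 CPM in the p53-ko libraries.

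Leukaemias with and without ICN were compared in the p53-ko background (4 against 4 mice, Miz1 wt and Vav). The genes with the largest rise with ICN included red cell genes. Slc4a1, the anion exchanger of red cells, lay at 2910 ± 1290 against 0.0933 CPM. Carbonic anhydrase Car1 (117 ± 74.5 CPM) and the red cell pyruvate kinase Pklr (29.4 ± 9.49 CPM) had no count without ICN, so they were at least 8210-fold and at least 2060-fold higher. Rhd, Epb42, Trim10 and Nxpe2 rose likewise, as did Rhag (pooled ratio 19000, counting interval 5260 to 157000). Of granule genes, Ngp lay at 256 ± 327 against 0.0265 CPM and Camp had a pooled ratio of 8720 (2410 to 72100). Among genes lower with ICN were the Wnt receptor Fzd10 (0.021 against 34.2 ± 25.9 CPM), Sall3 (0.059 against 36 ± 25.9 CPM), Lypd1 (0.0377 against 43.4 ± 45.2 CPM), Ly6k (0.397 against 110 ± 82.6 CPM), Tdrd5, Rps6ka6, Kif26a, Xlr, Kank4, Il17re, Ntf3 and Mgat5b. Without single libraries Xlr stayed called in 10 of 16 fits (adjusted p up to 0.254), Mgat5b in 14, and Kif26a and Ly6k in 15 each. In all, 2255 genes rose and 1939 fell, 24.01% of the genes tested. Zbtb17 fell (log2 -0.86, SE 0.21, adjusted p = 0.0125, up to 0.987 over all its alternatives), and Notch1 did not pass (-1.27, SE 0.46, 0.0649). Markers of other blood cells also differed between these libraries. Changes in this contrast therefore cannot be assigned to ICN in the leukaemia cells alone.

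Of 18 immature thymocyte and progenitor genes 12 rose and 0 fell, over all genes and adjusted over the list alone, among them Bcl11a (log2 7.48), Gata2 (7.03), Lmo2 (5.65; 89.5 against 1.88 CPM) and Lyl1 (5.62; 35.2 against 0.716 CPM). This call held with an estimated correlation (camera adjusted p = 3.75e-10, adjusted p = 0.0394 with an estimated correlation). In the same libraries the erythroid (median log2 11.09) and neutrophil markers (9.66) rose further, and Gata2, Lmo2, Lyl1 and Tal1 are also expressed in erythroid and progenitor cells, so the cells behind this rise are not known. Of 25 leukaemia genes 7 rose and 5 fell (8 and 6 adjusted over the list alone), with Tal1, a basic helix-loop-helix factor, at 229 against 0.0572 CPM (12.34) and Hoxa9 (4.74) higher, and Ccnd1 (-5.52), Gata3 (-2.01) and Bcl11b (-1.53) lower (camera adjusted p = 0.134). Of 29 double-positive and maturing thymocyte genes 7 rose, such as S1pr1 (5.07) and Cd69 (2.71). Another 7 fell, such as Ccr9 (-4.18), with 8 and 8 adjusted over the list alone (camera adjusted p = 0.973). Of 23 Notch targets 7 rose and 3 fell (8 and 4 adjusted over the list alone). Nrarp, a feedback inhibitor of Notch, lay at 202 ± 125 against 10.6 ± 5.44 CPM (4.27) and Hes5 at 6.07 against 0.0518 CPM (6.81), while Fjx1 (-2.71), Igf1r (-1.81) and Tcf7 (-0.85) fell (0.0894). Of 19 genes of IL-7 and JAK-STAT signalling 7 rose and 2 fell, the same numbers adjusted over the list alone, with the STAT5 targets Cish (5.88) and Pim1 (2.71) higher and Stat5a (-0.71) lower (0.0221, adjusted p = 0.314 with an estimated correlation).

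Of 34 interferon response genes 20 rose and 1 fell (23 and 1 adjusted over the list alone), with Rsad2 (log2 5.49), Oas3 (4.58) and Isg15 (3.84) higher and Usp18 (-1.31) lower (camera adjusted p = 6.99e-10, adjusted p = 0.375 with an estimated correlation). Of 24 genes of glycolysis and hypoxia 1 rose and 11 fell (1 and 13 adjusted over the list alone), among them Slc16a3 (-2.85), Bnip3 (-2.44) and Slc2a1 (-1.65) (0.000128, adjusted p = 0.375 with an estimated correlation). Of 21 cholesterol synthesis genes 0 rose and 7 fell, also adjusted over the list alone, such as Sqle (-1.12) (0.0229, adjusted p = 0.523 with an estimated correlation). Several lists moved both ways or little and did not pass camera. Of 40 p53 targets 7 rose, such as Pmaip1 (3.56), and 5 fell, such as Tnfrsf10b (-1.94), also adjusted over the list alone (0.78). Of 17 Bcl2 family genes 6 rose, such as Bcl2l2 (2.23) and Bcl2 (1.44), and 2 fell, Bok (-3.89) and Bik (-2.54), also adjusted over the list alone (0.13). Of 38 cell cycle genes 5 rose, among them Ccne1 (1.67) and Mki67 (0.95), in both adjustments (0.212). Of 18 reported Miz1 targets 2 rose, Hhex (2.80) and Bcl2, and 3 fell, Cdkn1c (-3.43), Mxd4 (-1.32) and Itga6 (-0.68), in both adjustments (0.984).

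Of 23 nucleoside metabolism genes 6 rose and 2 fell (6 and 3 adjusted over the list alone), with Samhd1 (log2 3.92) higher (camera adjusted p = 0.104). Of 37 autophagy genes 3 rose, such as Wipi1 (4.86), and 2 fell, such as Atg14 (-1.31), with 2 and 2 adjusted over the list alone (0.429). Of 80 ribosomal protein genes 5 rose and 4 fell (3 and 3 adjusted over the list alone; 0.973), with Rpl22l1 (1.51) higher. Of 58 ribosome biogenesis genes 0 rose and 3 fell (0 and 1 adjusted over the list alone; 0.429), among them Tmem97 (-0.85). Of 20 genes of the unfolded protein and stress response 1 rose and 1 fell (1 and 0 adjusted over the list alone; 0.78), with Ppp1r15a (3.84) higher. Of 18 immediate early genes 5 rose and 0 fell in both adjustments, such as Egr1 (1.64) and Zfp36 (1.60) (0.181). None of the 8 mitochondrially encoded genes passed in either adjustment (0.905).

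Markers of other blood cells moved with ICN. Of 18 erythroid markers 17 rose over all genes and 18 adjusted over the list alone, and the call held with an estimated correlation (camera adjusted p = 1.59e-61, adjusted p = 0.0394 with an estimated correlation). All 19 neutrophil markers rose in both adjustments (2.57e-14, adjusted p = 0.317 with an estimated correlation). Of 19 B cell markers 12 rose (15 adjusted over the list alone) and 0 fell (6.08e-06, adjusted p = 0.413 with an estimated correlation). Of 18 NK and cytotoxic markers 9 rose (10 adjusted over the list alone), such as Klrb1c (log2 6.46) and Gzmb, and 2 fell, Sox13 (-5.34) and Tbx21 (-3.12) (0.000809, adjusted p = 0.314 with an estimated correlation). Of 21 macrophage markers 5 rose, such as Csf1r (1.90), and 1 fell, Apoe (-1.10), in both adjustments (0.104). Of 18 endothelial and stromal markers 4 rose, such as Vwf (6.27), and 3 fell, such as Dcn (-3.89), in both adjustments (0.78). Of 9 thymic epithelial markers 1 rose, Prss16 (3.97), and 2 fell, Krt8 (-5.00) and Ctsl (-1.89), with 1 and 3 adjusted over the list alone (0.155). Mean log2 CPM of the erythroid markers lay at 7.46 to 9.57 in the 12 ICN libraries and at -1.4 to -0.02 in the 4 others. The ICN count of 4194 was 2585 and 2524 without replicate 1 and 2 of ICN Vav p53-ko and 2360 in a fit of the compared groups only, and the call on Zbtb17 was lost without replicate 1 of ICN Vav p53-ko (adjusted p = 0.0559, range 0.00364 to 0.0559). With erythroid and granulocyte scores as covariates, which nearly follow the ICN groups, 0 genes were called by edgeR, with 844 at an unadjusted p under 0.05. Without ICN, 0 of 19 neutrophil and 4 of 18 erythroid markers reached 1 CPM in every library. That level was reached in each of them by 26 of 29 double-positive and maturing and 9 of 18 immature thymocyte genes.

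**Figure D3:**
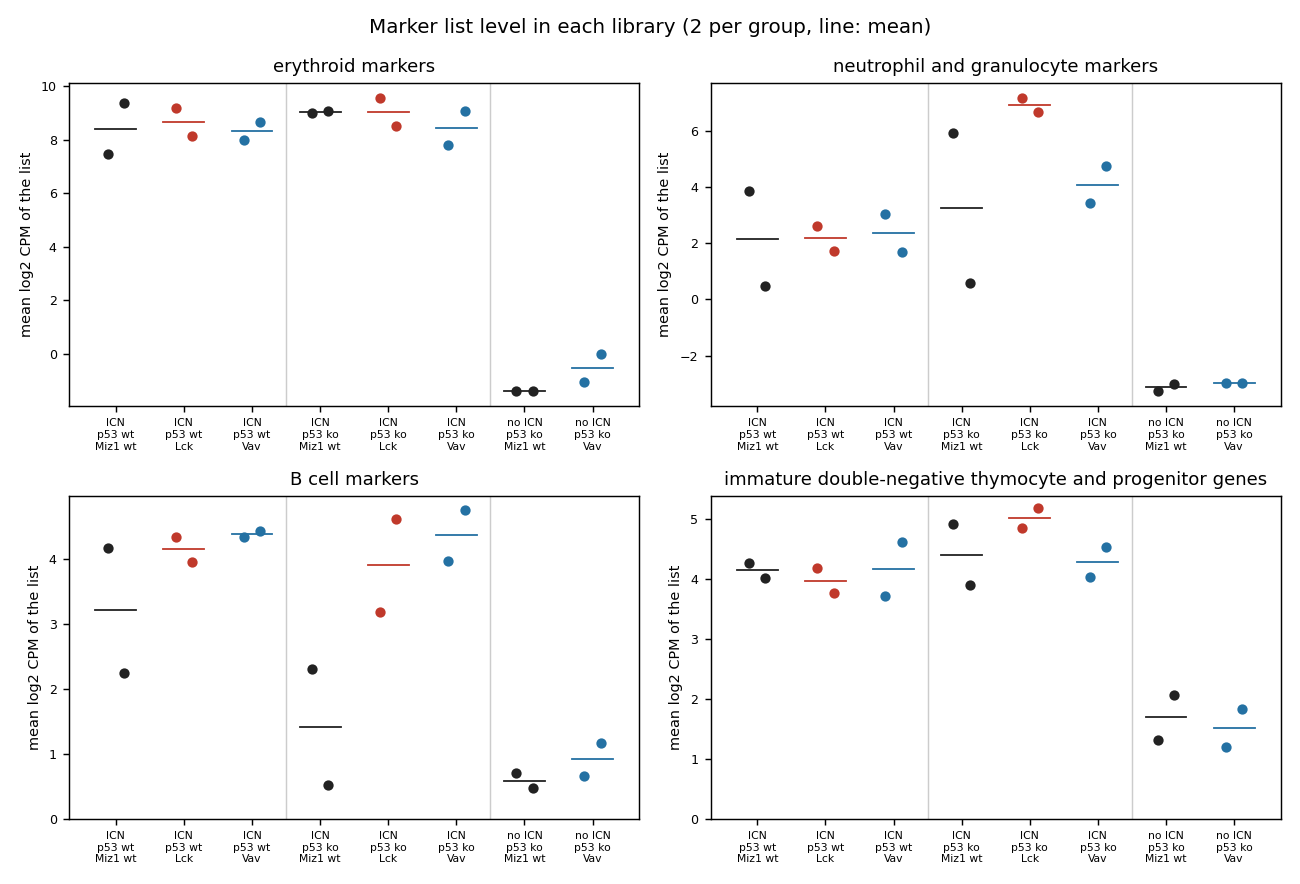
Mean log2 CPM (y axis) of the erythroid, neutrophil, B cell and immature thymocyte lists in each library, 1 point per mouse and a line at the group mean, for the 8 groups on the x axis. The erythroid mean lies at 7.46 to 9.57 in the ICN libraries and at -1.4 to -0.02 in the libraries without ICN.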

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

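The list tests of this part were set before the data were examined, and only their repeats without single libraries were chosen after the results were seen.

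The effect of Miz1 deltaPOZ differed between p53-ko and p53-wt ICN leukaemias for 4 of 26 lists, by a test of the difference itself. The median log2 change of B cell markers with deltaPOZ was larger in the p53-ko background (2.01 against 0.72, median difference 2.07, camera adjusted p = 1.39e-10), as was that of ribosome biogenesis and MYC target genes (0.34 against 0.09, difference 0.21, adjusted p = 0.000131), although 0 members of either list passed in p53-wt leukaemias. The median log2 changes of neutrophil markers had opposite signs, with 0.54 in p53-ko and -0.84 in p53-wt leukaemias (difference 1.38, adjusted p = 4.76e-05), and so had those of mitochondrially encoded genes, with -0.65 and 0.28 (difference -0.95, adjusted p = 0.00021). Each of the 4 had an adjusted p = 0.944 with an estimated correlation. The libraries behind these values were uneven. The neutrophil mean was 5.93 and 0.6 in the ICN Miz1-wt p53-ko pair and 3.85 and 0.48 in the ICN Miz1-wt p53-wt pair (mean log2 CPM), and the B cell means of the same pairs were 2.3 and 0.52, and 4.17 and 2.25. The neutrophil mean of the ICN deltaPOZ p53-wt libraries lay between those of their Miz1-wt pair, at 1.68 to 3.05. By that measure the neutrophil markers did not fall with deltaPOZ in p53-wt leukaemias, so the sign there depends on the measure. Over the fits that left out 1 library each, the adjusted p ran from 7.89e-24 to 0.253 for B cell markers, from 7.04e-36 to 0.604 for neutrophil markers, from 1.75e-15 to 0.206 for ribosome biogenesis genes and from 1.54e-05 to 0.427 for mitochondrial genes. Without replicate 1 of ICN Miz1-wt p53-ko the ribosome biogenesis list changed direction (adjusted p = 0.206), and without replicate 1 of ICN Miz1-wt p53-wt or replicate 2 of ICN Miz1-wt p53-ko the neutrophil list did (0.604 and 0.563). No explanation was tested for these differences.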

How the results depend on the processing

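The additive model, the cell scores as covariates, and the list tests without single libraries or with other scaling were chosen after seeing the data. The other alternatives were planned. Median-of-ratios scaling and removal of receptor segments kept every count of genes within 1.5 times. No paired analysis was possible because no mouse numbers are shared between groups. The mouse numbers in the titles fall in separate ranges for ICN p53-wt, ICN p53-ko and noICN mice. In both ICN backgrounds the Lck numbers also lie apart from those of the Miz1-wt and Vav mice. Whether these ranges mark cohorts or litters is not given in the sources used here. If they do, the p53, ICN and suffix contrasts cannot be told apart from cohort or litter. The same holds for the Lck part of the Miz1 contrasts in ICN mice. Where an arm keeps 1 library, the lone sample is assumed to vary like the other groups.

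Counts are given in the order deltaPOZ in ICN p53-wt, in ICN p53-ko, without ICN, averaged, and difference, then p53, ICN and suffix. With no filter on low counts the first 5 were 211, 464, 746, 502 and 378, p53 gave 1588 and the suffix 277. That fit gave infinite prior degrees of freedom over 30095 genes, so all genes shared a common spread. With DESeq2 they were 16, 127, 241, 134, 30, 1065 and 22 (the ICN count stayed within 1.5 times). The cause was not tested on the real counts. On simulated counts DESeq2 called 51 to 79 unchanged genes per contrast where edgeR called 0 to 8, so its extra calls can be false ones. A fit of the compared groups only gave 2 genes for ICN p53-ko, 149 for p53 and 2360 for ICN, from fewer libraries. Pooling Lck and Vav gave 1 gene for the difference of the Miz1 effects (the cause was not tested). It gave 3 genes for the average, of which 2 were shared, and 37 for p53, of which 21 were shared. The additive model called 0 genes for the average (the cause was not tested).

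With cell scores as covariates 0 genes were called for ICN p53-ko, where Sox11 kept its direction. The same covariates left 1 gene for the average (Snx18) and 2 for p53 (Cdkn2a and Eif5al3-ps). They left 0 for ICN, where the scores nearly follow the groups and 2706 of 4194 genes kept their direction. Xlr (log2 11.94, adjusted p = 0.99), Ly6k (10.38, 0.987) and Notch1 (2.47, 0.987) changed sign there.

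Leaving out 1 library gave 0 to 1 genes (ICN p53-wt), 0 to 3 (ICN p53-ko), 0 to 108 (without ICN), 0 to 20 (average), 0 to 0 (difference), 2 to 132 (p53), 2524 to 4643 (ICN) and 0 to 1 (suffix). Called single genes kept their call in 536 such fits and lost it in 216, with none reversed.

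Of 64 list calls 3 held with an estimated correlation, fry made 19 calls, of which 11 were shared, and other scaling kept 63. Without replicate 1 of ICN Miz1-wt p53-ko 60 lists were called. The ribosomal protein (adjusted p = 0.402), ribosome biogenesis (0.845) and mitochondrial lists (0.845) in ICN p53-ko and the ribosome biogenesis difference (0.206) then changed direction. The neutrophil difference changed direction without replicate 1 of ICN Miz1-wt p53-wt (0.604) or replicate 2 of ICN Miz1-wt p53-ko (0.563). The 4 lists whose Miz1 effect differed ran from 7.89e-24 to 0.253 (B cell), 7.04e-36 to 0.604 (neutrophil), 1.75e-15 to 0.206 (ribosome biogenesis) and 1.54e-05 to 0.427 (mitochondrial) without single libraries. The cause was not tested. Depth limits single genes near the floor: with 3 counts in deltaPOZ mice the ratio of Sox11 is known only to within 206 to 2930.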

Other observations

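The tests on splits of the libraries, covariates, chromosomes, quartiles, erythroid levels and the set of 8 genes were chosen only after the results were seen, and the list tests with camera were planned.

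Members of further lists differed between p53-ko and p53-wt ICN leukaemias, adjusted over the list alone, beside the rise of all 19 neutrophil and 11 of 21 macrophage markers, and the cells behind them are not known. Of 18 NK and cytotoxic markers Gzmb (log2 2.27), Tyrobp (1.63), Fcer1g, Nkg7 and Klrk1 rose, while Klrb1c fell (camera adjusted p = 0.00532, adjusted p = 0.552 with an estimated correlation). Of the reported Miz1 targets, Cdkn2b (2.76), a cell cycle inhibitor next to Cdkn2a, and the myeloid factors Cebpa (1.80) and Cebpd (2.05) rose (0.0478, adjusted p = 0.552 with an estimated correlation). Spi1, Gata2 and Erg, factors of blood progenitors, rose in the immature list and Myb fell (0.0478, adjusted p = 0.552 with an estimated correlation). Samhd1 (0.83), which breaks down nucleotides and nucleoside analogues, Cda (2.10) and Dut (0.67) rose (camera adjusted p = 0.204 for their list), and the early response genes Egr1 (-1.33) and Egr2 (-1.86) fell (camera adjusted p = 0.753). The noncoding genes Gm12609 (4.07, adjusted p = 0.0143) and Gm12610 (3.11, adjusted p = 0.0217) rose beside Cdkn2a on chromosome 4, and the processed pseudogene Eif5al3-ps had the lowest p of all. These 3 were named after their values were seen.

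Without ICN, deltaPOZ libraries had higher values of the globins Hbb-bs (log2 3.42) and Hba-a2 (3.69) adjusted over the list alone, of Nr4a1 (2.39), an early gene of receptor signalling, and of the matrix gene Fn1 (2.80), with 2 mice per arm. Reads of genes that T cells rarely use stood apart in a pair of libraries. Of 1347 sensory receptor genes 618 had a count in ICN Miz1-wt p53-ko replicate 1 and 694 in ICN Vav p53-wt replicate 2, against 35 to 180 elsewhere. Satellite-like genes reached 24600 CPM in the former, against 2.44 to 4310 CPM in the other 15 libraries.

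Some genes with a low unadjusted p for deltaPOZ were shared between backgrounds that have no library in common. Their p-values came from 1 fit with a shared estimate of spread per gene. A gene with a small estimate can thus pass in several backgrounds, so the numbers for independent lists can be too low. At an unadjusted p under 0.01, 8 genes were lower in both the ICN p53-wt and the noICN contrast, against 0.419 for independent lists, and 6 were lower in both ICN backgrounds, against 0.264. Lower in ICN p53-ko and noICN mice were 2, against 0.445. Higher in both ICN backgrounds were 2, against 0.0915, in ICN p53-wt and noICN mice 0, against 0.184, and in ICN p53-ko and noICN mice 3, against 1.74. Opposite ways, 4 genes were lower in ICN p53-wt and higher in noICN mice, against 0.933, and 2 were lower in ICN p53-ko and higher in noICN mice, against 0.99. The 8 were Znhit3, Mmadhc, Gne, Eif2b3, Ambra1, Snx18, Hfm1 and Cox19. In the ICN p53-ko mice all 8 were lower (median log2 -0.59, fry adjusted p = 0.00413 over 6 contrasts of the set), and 5 passed when adjusted over these 8. The levels of these mice were not compared in the choice. Their libraries did enter the shared estimate of spread behind it, so these p-values are not an independent check. Of the 8, 6 lie on other chromosomes than Zbtb17, which argues against sequence linked to the targeted locus for these 6. For Gne and Eif2b3 on chromosome 4, against 0.519 by chance (Fisher exact p = 0.0908), it stays open. In ICN p53-ko leukaemias 7 of the 8 were higher in Lck than in Vav mice (median 0.30, fry adjusted p = 0.0477), most of all Snx18 at 40.2 against 13.3 CPM. In the same libraries the neutrophil mean was 7.19 and 6.69 in Lck against 3.43 and 4.74 in Vav mice, and the macrophage mean 4.34 and 4.6 against 3.18 and 3.52. The share of the Miz1-wt level regained was uneven, from -2.49% (Gne) and 17.6% (Hfm1) to 67.5% (Snx18), the difference from the p53-wt pair was not past the threshold (fry adjusted p = 0.214), and no cause was tested.

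Blood cell genes were far higher in all ICN libraries. A lower share of leukaemia cells with an unchanged mix of other cells is argued against, because the lower quartile of the erythroid fold changes lay 6.84 above the upper quartile of the endothelial and stromal ones (log2 8.79 against 1.95). The lowest value of Hba-a1, Hbb-bs, Alas2 and Slc4a1 over the 12 ICN libraries was 220 CPM, and the highest without ICN 22.2 CPM, which is consistent with erythroid cells in the ICN samples. Of 18 erythroid and 19 neutrophil markers 0 belong to another list. The organ sampled could differ between the groups and is not in the labels.

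The 34 genes called between p53 genotypes could reflect granulocyte and erythroid content. Cdkn2a kept an adjusted p of 0.0253 with both scores as covariates (range over all its alternatives 5.85e-108 to 0.0253), which argues against cell content as its whole cause. Trp53 lost its call (log2 -2.06, SE 0.24, then -1.87, SE 0.33), but it lay at 7.3 to 21.8 CPM in the 4 p53-ko libraries without ICN, where both scores were lowest (neutrophil mean -3.26 to -2.97), against 70.2 to 113.5 CPM with p53, which argues against cell content. The other 31 genes that lost their call kept a median of 89.7% of their log2 change while the median SE rose from 0.30 to 0.42, so for them cell content and genotype cannot be told apart. Of the called genes other than Trp53, 28 of 33 lay on other chromosomes, which argues against linked sequence for these 28. For the 5 on chromosome 11, against 2.77 by chance (Fisher exact p = 0.194), it stays open. That test takes no account of position. Of the 5, Ybx2 (69935796 to 69941605, log2 -3.84) lay nearest to Trp53 (69580359 to 69591873).

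For this p53 contrast 4 of 100 splits, drawn from 108 possible and counting the real one, called at least the real 34 genes. That share lies under 0.05 among the splits drawn. However, 2 more among the 8 not drawn would bring the share above it. Other splits called 149, 146 and 41 genes, so chance cannot be excluded for the count. The number drawn, here and for the averaged Miz1 contrast, was raised to 100 after a first count was seen. The highest other split called 149, which points to a structure of the samples. The splits that called 149 and 146 genes ranked 1 and 3 by the gap of the neutrophil score (3.49 and 3.03, against 2.53 and rank 5 for the real one), but those ranked 2 and 4 (3.05 and 2.59) called 0, so neutrophil content alone does not set the count.

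For the ICN contrast 1 of the 35 splits of its 8 libraries, the real one, called as many genes (4359 in this fit) and the highest other called 6. That is the smallest share 35 splits can give, so it argues against chance for the count without excluding it. The splits do not tell ICN from anything else that differs between these groups. For the averaged Miz1 contrast 17 of 100 splits called at least as many genes as the real 3, so chance cannot be excluded for the count. The highest other called 144 and the next 14, and that single split points to a structure of the samples. It put the 2 libraries with the highest mitochondrial share of each background on the same side, the largest gap of all 1350 arrangements (0.41 percentage points, against 0.05 for the real one), and 6 arrangements were as extreme in library size. The split with the next gap (0.40) called 6, and no cause was tested. For the suffix contrast the real split called 0 genes, so 35 of 35 splits reach it by definition and this decides nothing. The highest other called 12 and parted p53-wt from p53-ko mice.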
